A study of Homo sapiens with 6 samples.

How the data were processed

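Small RNA of RMUG-S-ip1, a human mucinous ovarian cancer cell line, was profiled with the NanoString nCounter miRNA assay, in which probes capture each miRNA and a colour-coded reporter is counted without amplification. Per the labels, cells were transfected with a control siRNA or with an siRNA against PRKRA, total RNA was isolated with a column kit that keeps small RNA, and the same mass of RNA was taken from each sample. There were 3 samples per group. The labels give replicate numbers 1 to 3 in both groups but do not say whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. PRKRA encodes PACT, a double-stranded RNA-binding partner of Dicer; the PRKRA mRNA was not analysed here, so the degree of silencing is unknown.

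The values deposited by the authors are a processed signal per probe and sample, in a table of 822 rows. Of these, 800 are human miRNA rows, 5 are mRNA rows (RPL19, RPLP0, ACTB, GAPDH and B2M, named through a RefSeq reference table), 12 are control rows of the assay and 5 are further miRNA accessions found only in that table. A second table deposited by the authors holds log2 of the same signal for the 800 miRNA rows; its name calls it non-normalised, but 2 to the power of its values matched the signal table within 0.000234. A further table deposited by the authors compares the groups for 177 named miRNAs with a p-value, a Benjamini-Hochberg adjusted p-value, a log2 level per group and another number called a fold change, which is the ratio of the 2 log2 levels rather than of linear levels. The remaining 623 miRNA rows carry an accession with no name in the files. The software, its version, the background rule and the probes behind the scaling are not given in the sources used here.

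The steps between the deposited values show how they were made. Within a sample the values of the signal table are whole-number counts above a background, each multiplied by 1 factor for that sample, with low values set to a floor; in every library 100.0% of the values checked were whole within 0.1 after division by the recovered factor. The factors were 1.496, 1.525 and 1.315 for control siRNA replicates 1, 2 and 3, and 0.231, 1.09 and 0.469 for siPRKRA replicates 1, 2 and 3, a 6.61-fold range. The floor values were 1.5, 1.53, 1.32, 1, 1.09 and 1 in the same order. Control rows had the background subtracted and no factor applied. Of the 12 control rows, 5 had more than 100 counts in every sample in graded steps and are called graded control probes; the files do not state their class. No row could be assigned to the negative or the ligation controls.

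The design fixed before the data were examined assumed counts; because no deposited column holds counts, its stated fallback was used. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) was fitted to log2(value + 1) with group as the only term, over the miRNAs with a value of at least 30 in at least 3 of the 6 samples. These were 106 miRNAs. Fold changes are siPRKRA over control siRNA on the log2(value + 1) scale, which understates the change of low values. A miRNA was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Of 27 miRNA lists fixed beforehand (families, genomic clusters, cell type markers and arms), 13 had at least 3 tested members and were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. Totals and detection were compared by exact two-sided permutation tests, which with 3 against 3 samples cannot give a p under 0.1. Detection was counted above the floor and, as alternatives fixed beforehand, at a value of 30 and at 30 counts after scaling by the graded control probes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

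The miRNAs named were chosen by a rule fixed beforehand: the 12 largest rises and 12 largest falls among called miRNAs with no overlap between groups, or, where fewer than 5 were called in a direction, the 5 of that direction with the smallest unadjusted p as values that did not pass; miR-515-3p and miR-515-5p, which the study of these cells followed; the 5 miRNAs with the highest mean; and up to 4 tested members with the highest mean of each list discussed. miRNAs named outside the rule are said to have been chosen after their values were seen.

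The fit was tested on simulated data made from the same 106 miRNAs with 20 changed. Over 20 runs it found 69% of miRNAs changed by 1 log2 unit and 86% of those changed by 2, with 14 false calls in all. The 1 shifted list was found in 20 of 20 runs. The simulated miRNAs varied independently with normal noise, without a floor, scaling errors or an outlying library. These rates therefore need not hold for the real libraries. Alternatives fixed beforehand were other scalings (median of ratios, the 100 highest miRNAs, the graded control probes, the 5 mRNA rows and the total), no filter, no pseudocount, limma-voom on the recovered counts, the replicate number as a block, each sample left out, an estimated correlation in camera, and fry. Alternatives added after seeing the data were a value of at least 30 in all 6 samples, all miRNAs above the floor in at least 1 sample, a pseudocount of 10, values under 30 set to 30, library weights, the miRNA total without miR-4454 and miR-720, each sample left out of that total or of the median, and a correction for background subtracted in excess. For that correction, the number of counts that had to be added back to every library so that the control to siPRKRA ratio no longer depended on abundance was estimated. This was done over 83 miRNAs outside the C19MC cluster with a level between 40 and 3000. The ratios were of the control libraries to siPRKRA replicates 1 and 3, and the level was the mean of those replicates. The estimate does not draw on siPRKRA replicate 2. It was 25 counts (95% bootstrap interval 18 to 33, 200 draws), which assumes that no true change depends on abundance. On 10 simulations with none given the method returned -2.8 ± 2.9 (SD), and on 10 with 20 given it returned 16.7 ± 1.77. The simulations kept the same 83 miRNAs and did not repeat their choice by level in siPRKRA replicates 1 and 3. They therefore cannot show whether that choice biases the estimate.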

Results

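miRNA levels were measured with the nCounter assay in RMUG-S-ip1 cells, a human mucinous ovarian cancer line, 3 libraries after a control siRNA and 3 after an siRNA against PRKRA (siPRKRA). The question was which miRNAs differ when PACT, the Dicer partner encoded by PRKRA, is silenced. The deposited values are background-subtracted counts multiplied by 1 factor per library. Before that factor, the miRNA rows summed to 53137, 51641 and 56192 counts above background in control siRNA replicates 1, 2 and 3, and to 305261, 228546 and 142684 in siPRKRA replicates 1, 2 and 3. By the factors, a value in a control library rested on fewer counts than the same value in a siPRKRA library, least so for siPRKRA replicate 2. The factor of that library was 1.09, against 1.315 to 1.525 in control libraries, and miR-4454 and miR-720 made up 62.6% and 9.53% of its signal.

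**Figure D1:**
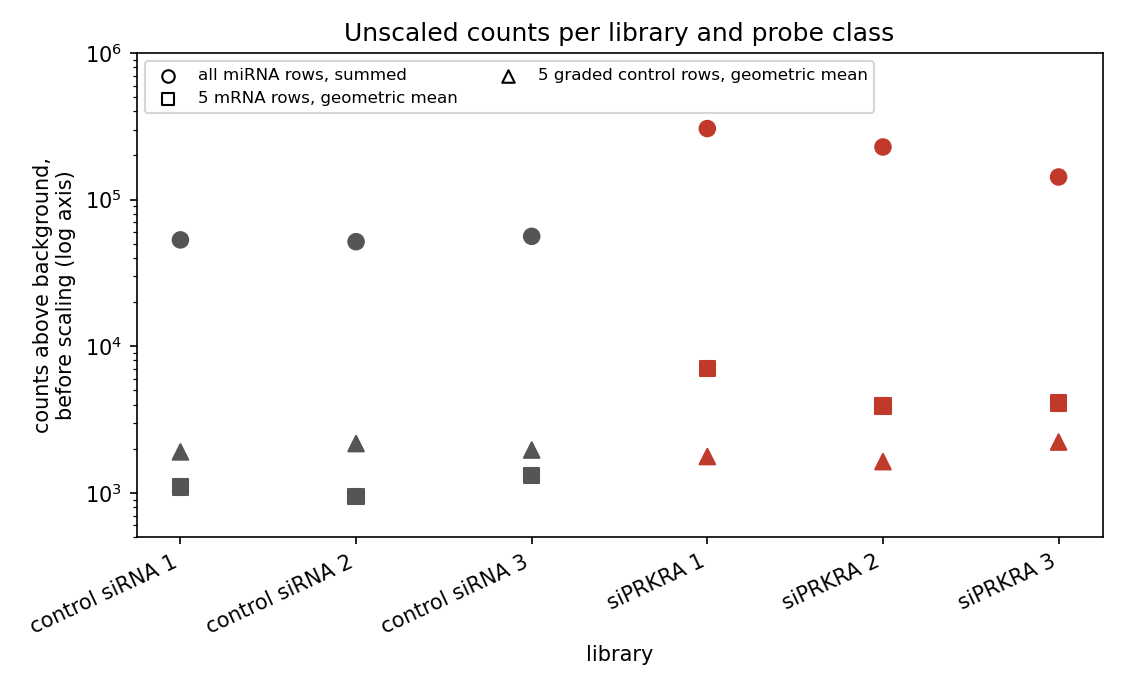
Counts above background before scaling (log axis) in each of the 6 libraries (grey, control siRNA; red, siPRKRA), as the sum over miRNA rows (circles), and as geometric means over 5 mRNA rows (squares) and 5 graded control probes (triangles). miRNA sums lay between 51641 and 56192 in control libraries and between 142684 and 305261 in siPRKRA libraries, while the graded control probes lay between 1633 and 2221 in all 6.

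The 5 highest mean values over the 6 libraries were those of miR-4454, let-7a-5p, miR-200c-3p, miR-720 and miR-29b-3p. let-7a-5p, of the let-7 family that restrains LIN28 and RAS, had a mean value of 8578 ± 494 (SD, n = 3) in control siRNA cells and 8875 ± 3209 (SD, n = 3) in siPRKRA cells. miR-200c-3p, which represses the mesenchymal regulators ZEB1 and ZEB2, stood at 5927 ± 511 (SD, n = 3) and 4529 ± 459 (SD, n = 3). miR-29b-3p stood at 4205 ± 298 (SD, n = 3) and 3395 ± 1027 (SD, n = 3). The means of miR-4454 and miR-720 were set by siPRKRA replicate 2. miR-4454 was at 155810 there, against 2331 to 5350 in the other libraries, and miR-720, since recognised as a tRNA fragment, was at 23707 against 542 to 1367.

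The comparison of siPRKRA with control siRNA addressed whether single miRNAs change when PRKRA is silenced. In limma 0 of the 106 tested miRNAs had an adjusted p under 0.05, 17 had an unadjusted p under 0.05 (8 higher, 9 lower in siPRKRA), and limma-voom on the recovered counts also gave 0. The smallest adjusted p was that of miR-186-5p, with values of 28.9 ± 2.75 (SD, n = 3) in control siRNA and 72.3 ± 4.399 (SD, n = 3) in siPRKRA libraries, a log2 fold change of 1.30 ± 0.20 (SE) at a limma adjusted p of 0.072, higher in 3 of 3 siPRKRA libraries than in any control library. Of the tested miRNAs, 44 had a higher and 62 a lower estimate. The values of 29 miRNAs (27.4%) did not overlap between the groups, 13 higher and 16 lower, where chance gives 10% for a single miRNA. The miRNAs share the same libraries and are not independent, and the share was not tested against 10%. With the estimated excess of subtracted background added back, the log2 fold change of miR-186-5p was 0.64 at a limma adjusted p of 0.263. That estimate assumes that no true change depends on abundance. miR-186-5p was among the miRNAs it was made from, so the smaller fold change is not an independent check.

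The other miRNAs with the smallest unadjusted p on the higher side were miR-193b-3p, miR-28-5p, miR-296-5p and the shared probe of miR-181b-5p and miR-181d, none of which passed. miR-193b-3p had values of 1.59, 1.53 and 11.02 in control libraries and 37.5, 64.2 and 35.6 in siPRKRA libraries (limma adjusted p = 0.175). miR-28-5p went from 48.6 ± 2.83 (SD, n = 3) to 81.9 ± 6.83 (SD, n = 3), a log2 fold change of 0.74 ± 0.17 (SE; limma adjusted p = 0.175). miR-296-5p had 9.07, 1.53 and 13.7 in control libraries and 43.0, 43.6 and 35.1 in siPRKRA libraries (limma adjusted p = 0.265). The miR-181b-5p and miR-181d probe had a log2 fold change of 0.72 ± 0.23 (SE). miR-193b-3p and miR-296-5p lay at or near the floor in the control libraries, where 1 count was worth 1.32 to 1.53 units of value. With the estimated background added back, the log2 fold change of miR-193b-3p went from 3.40 to 0.71 and that of miR-296-5p from 2.52 to 0.53. In that setting miR-28-5p was at 0.43 and the miR-181b-5p and miR-181d probe at 0.23. Both of these were among the miRNAs the estimate was made from, so their smaller values are not an independent check.

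On the lower side the smallest unadjusted p belonged to miR-24-3p, miR-361-5p, miR-200c-3p, miR-579 and miR-371a-3p, none of which passed, each at a limma adjusted p of 0.265. miR-24-3p stood at 553 ± 8.16 (SD, n = 3) in control and 435 ± 48.8 (SD, n = 3) in siPRKRA libraries, a log2 fold change of -0.35 ± 0.11 (SE). miR-361-5p had a log2 fold change of -0.36 ± 0.12 (SE) and miR-200c-3p one of -0.39 ± 0.13 (SE). miR-579 had the values 53.9, 127 and 47.8 against 12.8, 39.3 and 22.5. miR-371a-3p, known from pluripotent and germ cell tumours, had 40.5, 56.6 and 38.6 against 5.62, 30.6 and 12.6. Unscaled counts of miR-579 were 36.1, 83.1 and 36.4 against 55.3, 36.2 and 47.9.

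Which calls were made depended on single libraries and on the scaling. Without siPRKRA replicate 2, let-7b-5p, miR-302d-3p, miR-378e and miR-4516 (the last 2 named after their values were seen) had limma adjusted p values of 0.0137, 0.0137, 0.0217 and 0.0137, all lower in siPRKRA, and without control siRNA replicate 3 miR-186-5p and miR-193b-3p had 0.0407 and 0.0247, both higher. Scaling by the graded control probes in place of the authors' factors gave 22 changed miRNAs, all higher. These were tested against no change, so they include the common shift, a median of 1.61 log2 units over all tested miRNAs.

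**Figure D2:**
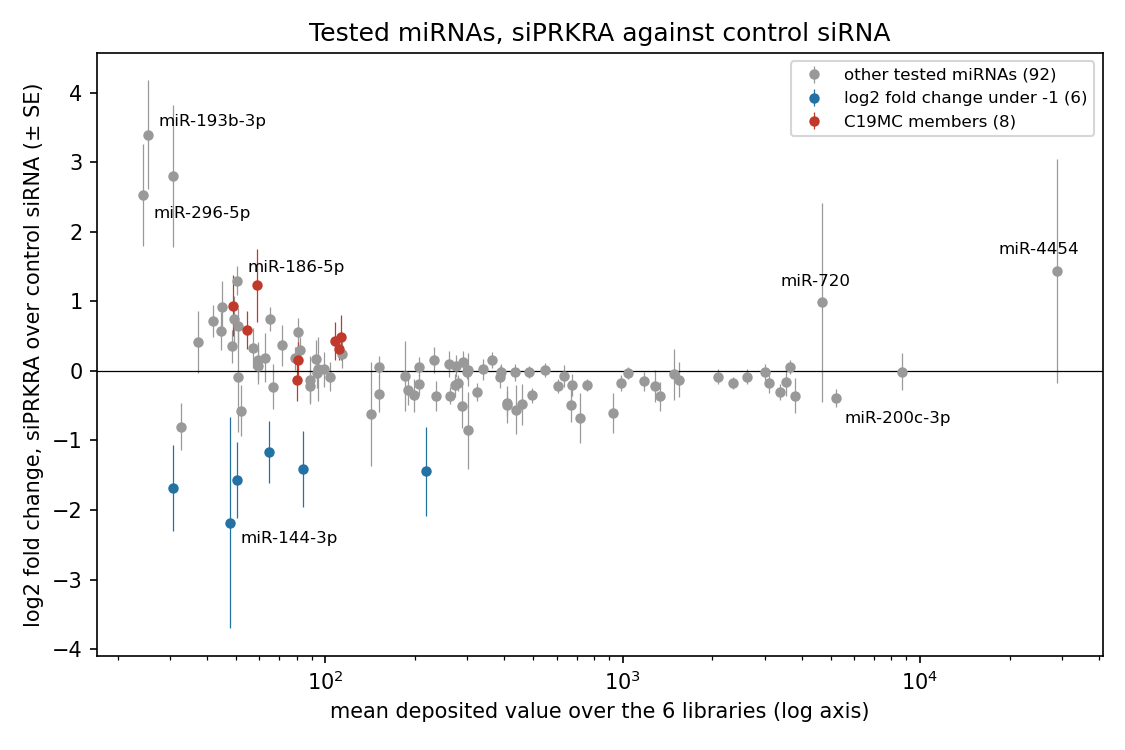
Log2 fold change of siPRKRA over control siRNA (y axis, ± SE) against the mean deposited value over the 6 libraries (x axis, log) for the 106 tested miRNAs, with 8 C19MC members in red and 6 miRNAs with a log2 fold change under -1 in blue. Of the estimates over 1 in size, those of miR-378e and miR-4454 lie above a mean value of 100, and the standard errors of miR-4454 and miR-720 are 1.61 and 1.43.

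miR-515-3p and miR-515-5p, the 2 arms of 1 precursor of the C19MC cluster, were the miRNAs the study followed. miR-515-3p was listed at the floor in all 3 control libraries (1.5, 1.53 and 1.32) and had values of 41.4, 16.5 and 28.1 in siPRKRA libraries. It did not reach 30 in 3 libraries and was therefore not among the 106 tested. Over all 198 miRNAs above the floor in at least 1 library, its difference in log2(value + 1) was 3.51 ± 0.59 (SE) at a limma adjusted p of 0.0595. The size of that difference rests on the floor and the pseudocount, as no control value lay above the floor. With an estimated 25 counts of subtracted background added back it was 0.44 ± 0.18 (SE) at 0.211. With no filter, fixed beforehand, miR-515-3p passed at a limma adjusted p of 0.0011. In that setting 635 miRNAs passed, 602 of them at the floor in every library. miR-515-5p, in contrast, had 82.5 ± 13.6 (SD, n = 3) in control and 78.5 ± 27.7 (SD, n = 3) in siPRKRA libraries, a log2 fold change of -0.12 ± 0.31 (SE) at a limma adjusted p of 0.856.

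Among the miRNA lists, the C19MC cluster was the only one of 13 that was shifted. C19MC is a primate-specific, imprinted cluster on chromosome 19 that is expressed mainly in placenta and stem cells. It was higher in siPRKRA cells, with a median log2 fold change of 0.46 over its 8 tested members (camera adjusted p = 0.0381), but at an adjusted p = 0.890 with an estimated correlation. Of the 8 members 7 had a higher and 1 a lower estimate, and 0 passed over all tested miRNAs or adjusted over the list alone. miR-522-3p stood at 93.8 ± 27.8 (SD, n = 3) in control and 132 ± 40.8 (SD, n = 3) in siPRKRA libraries, and miR-1323 at 99.5 ± 12.6 (SD, n = 3) and 123 ± 11.6 (SD, n = 3). The shared probe of miR-517c-3p and miR-519a-3p had a log2 fold change of 0.44 ± 0.27 (SE), and miR-512-5p one of 0.16 ± 0.26 (SE). Of 13 named members at the floor in all control libraries, 6 were above it in all siPRKRA libraries. Over all named miRNAs these numbers were 44 and 14. Since 0 named miRNAs were at the floor in all siPRKRA libraries, some rise of such members was fixed by the naming. Because miR-515-3p and its cluster were of interest to the study on these samples, the direction of this list is not independent evidence.

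The C19MC call was lost in limma's camera without control siRNA replicate 2 (median log2 fold change 0.27, adjusted p = 0.244), control siRNA replicate 3 (0.43, adjusted p = 0.162), siPRKRA replicate 1 (0.29, adjusted p = 0.363) or siPRKRA replicate 3 (0.41, adjusted p = 0.145), and when values were scaled by the 100 highest miRNAs (0.52, adjusted p = 0.0578). It held without control siRNA replicate 1 (0.54, adjusted p = 0.0025) or siPRKRA replicate 2 (0.57, adjusted p = 0.0024). Over 24 alternatives its adjusted p ranged from 8.57e-25, with no filter, to 0.903, and 11 of them were under 0.05. Its median was -0.10 with values scaled by the 5 mRNA rows and -0.0092 in limma-voom. These settings moved the median of all tested miRNAs to -0.62 and -0.50. The list then lay 0.53 and 0.49 above that median, against 0.52 in the deposited scaling. Because a factor per library shifts all miRNAs nearly alike, this distance could hardly change and says nothing on robustness. With each library left out the distance ranged from 0.33 to 0.64, and with background added back it was 0.25. Over miRNAs above the floor in at least 1 library it was 0.65, and -0.025 with background added back to these. The siPRKRA libraries held more counts than the control libraries, and siPRKRA replicate 2, which correlated with the other libraries at 0.833 to 0.884 across miRNAs, lay within the control range for miR-521, named after its values were seen (38.2 against 21.5 to 50.9), and for miR-522-3p (85.9 against 67.3 to 123).

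**Figure D3:**
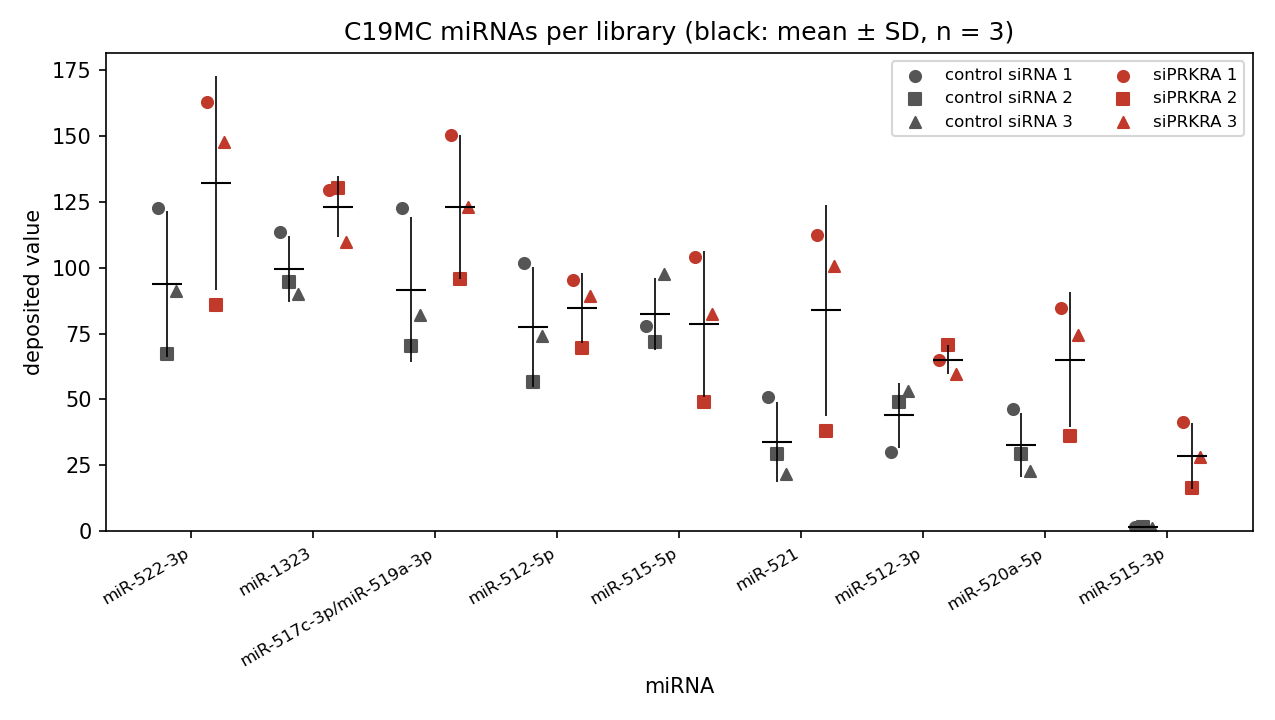
Deposited values (y axis) of the 8 tested C19MC miRNAs and of miR-515-3p (x axis) in each library (grey, control siRNA; red, siPRKRA; marker shape, replicate number), with black bars for mean ± SD (n = 3). miR-515-3p lies at the floor in the 3 control libraries and between 16.5 and 41.4 in the siPRKRA libraries.

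The other 12 lists did not pass, at camera adjusted p values between 0.531 and 0.977. The let-7 family had 8 tested members, 2 with a higher and 6 with a lower estimate, and a median log2 fold change of -0.04, while the direction of its camera test was up. let-7g-5p stood at 2150 ± 94.7 (SD, n = 3) in control and 2027 ± 176 (SD, n = 3) in siPRKRA libraries, let-7e-5p at 1589 ± 114 (SD, n = 3) and 1513 ± 556 (SD, n = 3), and let-7b-5p at 1438 ± 57.7 (SD, n = 3) and 1530 ± 869 (SD, n = 3). The miR-17-92 cluster and its paralogs, which MYC induces, had 1 of 8 members with a higher and 7 with a lower estimate and a median of -0.34. Among them, miR-19b-3p had the values 930, 880 and 757 against 725, 295 and 709, and the shared probe of miR-106a-5p and miR-17-5p had a log2 fold change of -0.17 ± 0.12 (SE). miR-93-5p had a log2 fold change of -0.20 ± 0.16 (SE), and the shared probe of miR-20a-5p and miR-20b-5p one of -0.48 ± 0.25 (SE).

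The epithelial miR-200 family had 3 tested members and a median log2 fold change of -0.39. miR-141-3p, which is made from the same primary transcript as miR-200c-3p, had 470 ± 55.2 (SD, n = 3) in control and 344 ± 67.0 (SD, n = 3) in siPRKRA libraries, whereas miR-200b-3p had 61.5 ± 11.9 (SD, n = 3) and 81.5 ± 27.5 (SD, n = 3). The miR-23, miR-27 and miR-24 clusters had a median of -0.18 over 5 members, 4 of them with a lower estimate. miR-23a-3p stood at 2486 ± 87.2 (SD, n = 3) and 2201 ± 30.2 (SD, n = 3), miR-27b-3p at 469 ± 52.0 (SD, n = 3) and 346 ± 108 (SD, n = 3), and miR-23b-3p at 297 ± 17.8 (SD, n = 3) and 263 ± 20.6 (SD, n = 3). None of these 4 lists had a member past 0.05 adjusted over the list alone.

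Other lists had too few tested members for a list test. Of the pluripotency clusters miR-371 to miR-373 and miR-302, 2 members were tested, miR-371a-3p and miR-302d-3p (116 ± 17.4 in control and 52.3 ± 41.9 in siPRKRA libraries, SD, n = 3). Both passed adjusted over the list alone in limma (0.0404), and 0 passed over all tested miRNAs. Before scaling, their counts differed little between the groups, at 27.1, 37.1 and 29.4 in control and 24.3, 28.2 and 26.9 in siPRKRA libraries for miR-371a-3p, and at 65.1, 86.1 and 91.4 against 94.4, 92.2 and 74.9 for miR-302d-3p. In deposited values miR-302d-3p lay within the control range in siPRKRA replicate 2 (100.05 against 97.3 to 131), and with scaling by the graded control probes, which moved the median of all tested miRNAs to 1.61, the log2 fold changes were -0.11 for miR-371a-3p and 0.22 for miR-302d-3p. Relative to that median they were lower by about as much as in the deposited scaling, at -1.72 against -1.62 and at -1.38 against -1.35. A factor per library shifts all miRNAs nearly alike, so this likeness was fixed in advance and lends no support to a fall. Of the miR-181 family 2 members were tested, both with a higher estimate. The miR-181b-5p and miR-181d probe passed adjusted over the list alone (0.0401), miR-181a-5p did not (342 ± 16.9 in control and 383 ± 44.4 in siPRKRA libraries, SD, n = 3), and 0 passed over all tested miRNAs. Of blood and endothelial cell markers, which this culture should lack, 2 were tested and 0 passed. Endothelial miR-126-3p had 220 ± 7.73 (SD, n = 3) and 194 ± 29.2 (SD, n = 3), and erythroid miR-144-3p varied between 6.07 and 151 in control and between 1.09 and 39.4 in siPRKRA libraries.

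To see whether all miRNAs shifted together when a Dicer partner was silenced, the miRNA total was set against the other probe classes before scaling. Relative to the graded control probes, the tested miRNAs summed to 4.31-fold more in siPRKRA than in control libraries, with mean log2 ratios of 6.84 ± 0.75 (SD, n = 3) and 4.73 ± 0.15 (SD, n = 3; exact permutation p = 0.1, the smallest possible). Without miR-4454 and miR-720, both highest in siPRKRA replicate 2, the sum was 2.89-fold higher, and the median of the tested miRNAs was 2.68-fold higher (exact permutation p = 0.1 for both). Without siPRKRA replicate 1 these 2 values were 1.92-fold and 1.69-fold. The 5 mRNA rows were 4.69-fold higher relative to the same probes (exact permutation p = 0.1). Relative to the mRNA rows the miRNA total did not differ beyond the spread, at log2 ratios of 5.46 ± 0.38 (SD, n = 3) in siPRKRA and 5.59 ± 0.18 (SD, n = 3) in control libraries (exact permutation p = 0.7). That log2 difference, -0.12, was -0.70 without miR-4454 and miR-720 and -0.81 with the median of the tested miRNAs (exact permutation p = 0.2 for both). Without siPRKRA replicate 2 these became -0.33, -0.30 and -0.35, and the first was 0.056 without siPRKRA replicate 3.

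More miRNAs were detected in siPRKRA libraries. Of the 800 miRNA rows, 125, 125 and 130 lay above the floor in control libraries and 174, 165 and 166 in siPRKRA libraries, a difference of 41.7 between the means (exact permutation p = 0.1, the smallest possible). The size of the difference depended on the threshold. At a fixed value of 30 it was 8 (102, 101 and 101 against 109, 113 and 106), and at 30 counts after scaling by the graded control probes it was 37.3 (94, 90 and 94 against 151, 115 and 124; exact permutation p = 0.1 for both). In all control libraries at the floor and in all siPRKRA libraries above it were 14 miRNAs, among them miR-515-3p, and 0 miRNAs showed the opposite.

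The authors' deposited table lists 2 of its 177 miRNAs with an adjusted p under 0.05, miR-186-5p and the C19MC member miR-519c-3p, each at 0.0439. miR-519c-3p, named after its values were seen, was at or near the floor in control libraries (1.5, 1.69 and 1.32) and had 19.02, 12.1 and 14.5 in siPRKRA libraries. The sign of the fold change in the authors' deposited table was that of the fit for 105 of 106 tested miRNAs (99.1%, exact Clopper-Pearson 95% interval 94.9% to 100.0%). Across these miRNAs, which are not independent replicates as the interval assumes, the log2 differences correlated at a Pearson r of 0.992 and a Spearman rho of 0.988. Both sides were computed from the same deposited values, so this likeness was largely fixed in advance and says nothing on reproducibility. In the authors' deposited table miR-515-3p has a fold change of 8.90, which is the ratio of log2 levels of 4.74 and 0.533, and an adjusted p of 0.193. Of the 46 miRNAs whose entry in that column exceeds 2 in size in the authors' deposited table, 34 were at the floor in all 3 control libraries.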

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

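The tests in this part were chosen after the results were seen. One row of the value table outside the comparisons, the miRNA accession MIMAT0001605, was higher in siPRKRA than in control libraries. It has no name in the files and, like the control rows, was not scaled by the authors. Whether it is a human miRNA or a control probe is not stated, so its rise is not read as a miRNA response. The other rows of this kind stood at 1 in every library, except for 1 value of 2.35 in siPRKRA replicate 1. The values of MIMAT0001605 were 102.35, 20.17 and 43.88 in siPRKRA replicates 1, 2 and 3, against 1, 1 and 6.38 in control libraries. Multiplied by the factor of each library they become 23.6, 21.9 and 20.6 against 1.496, 1.53 and 8.39. Among the 623 miRNA rows with no name, 20 were above the floor in siPRKRA replicate 2, against 0 to 3 in each other library, and 18 of them in that library alone, with values of up to 40.4.

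siPRKRA replicate 2 stood apart from the other libraries, with 62.6% of its miRNA signal in miR-4454. A wrong scaling factor alone is argued against: after centring, 12 tested miRNAs were higher and 7 lower by over 1 log2 unit than in the other siPRKRA libraries, where those 2 libraries differed from each other by that much for 3. A different mix of RNA classes in the extract stays open. The deposited, scaled mRNA values were 2.54-fold higher than in the other 5 libraries, but the direction depends on the scale: in unscaled counts they were below those of both other siPRKRA libraries (3900 against 7039 and 4100), and the log2 ratio of the miRNA total to the mRNA rows was the highest of the 6 libraries, at 5.87, and the lowest, at 3.99, without miR-4454 and miR-720. The labels name nothing that sets this library apart, so no biological explanation was tested.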

How the results depend on the processing

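Choices added after seeing the data were both filters other than no filter, the pseudocount of 10, values set to 30, the added-back background, library weights, the total without miR-4454 and miR-720, and leaving out each library from that total or from the median. The cause of the differences was not tested unless given. The count of changed miRNAs, 0 in limma, was 22 (all higher) with scaling by the graded control probes, 1 (lower) with the 5 mRNA rows, 635 with no filter (602 of them at the floor in every library, where the floor differs between groups by construction), 1 with values under 30 set to 30, 8 (4 higher, 4 lower) with library weights, and 0 to 4 with each library left out: 4 without siPRKRA replicate 2, 2 without control siRNA replicate 3, 0 otherwise. It was 0 in every other setting. The count of shifted lists, 1, was 14 with no filter, for the same reason, and 0 with limma-voom, with scaling by the 100 highest miRNAs, the graded probes, the mRNA rows or the total, with background added back, with an estimated correlation, with fry, and without either control siRNA replicate 2 or 3 or siPRKRA replicate 1 or 3 (range 0 to 1). These scalings moved the median of all tested miRNAs from -0.06 to 1.61 (graded probes), -0.62 (mRNA rows), -0.50 (total) and -0.50 (limma-voom). The C19MC median, 0.46, was -0.0092 with limma-voom and -0.10 with the mRNA rows. That is 0.49 and 0.53 above the median of all tested miRNAs (0.52 in the deposited scaling), a distance that a factor per library can hardly change. With background added back the C19MC median was 0.31, which is 0.25 above that of all tested miRNAs. With background added back over miRNAs above the floor in at least 1 library it was -0.20, at a distance of -0.025.

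Whether the replicate numbers pair the samples cannot be told from so few libraries. Deviations of same-numbered libraries correlated at 0.17, -0.09 and -0.07, and those of differently numbered libraries at -0.20 to 0.27. With the replicate block 0 miRNAs and 1 list passed, C19MC, at a camera adjusted p of 0.0049 against 0.038 without the block. The planned edgeR fit on deposited counts, the ligation controls, background subtraction and thresholds from negative controls were not run. No deposited column holds counts, background is already subtracted, and no such rows are identified. The counts recovered here are above background and floored, and of the count methods only limma-voom was applied to them.

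With the graded probes, log2 fold changes that were negative became 1.31 for miR-24-3p, 1.31 for miR-361-5p, 1.28 for miR-200c-3p, 0.047 for miR-579, 1.53 for miR-515-5p, 1.66 for let-7a-5p, 1.31 for miR-29b-3p, 1.58 for let-7g-5p, 1.54 for let-7e-5p, 1.62 for let-7b-5p, 1.20 for miR-141-3p, 1.49 for miR-106a-5p/miR-17-5p, 0.99 for miR-19b-3p, 1.46 for miR-93-5p, 1.18 for miR-20a-5p/miR-20b-5p, 1.49 for miR-23a-3p, 1.18 for miR-27b-3p, 1.49 for miR-23b-3p, 0.22 for miR-302d-3p and 1.47 for miR-126-3p, beside the common shift of 1.61. With the mRNA rows, miR-522-3p was -0.072, miR-1323 -0.25, miR-517c-3p/miR-519a-3p -0.12, miR-512-5p -0.40, miR-181a-5p -0.40 and miR-200b-3p -0.18; with limma-voom, miR-1323 was -0.15, miR-517c-3p/miR-519a-3p -0.026, miR-512-5p -0.29, miR-181a-5p -0.26 and miR-200b-3p -0.063; with the total, miR-1323 was -0.12, miR-512-5p -0.27, miR-181a-5p -0.28 and miR-200b-3p -0.056. With background added back, over either set of miRNAs, let-7a-5p was 0.23, let-7g-5p 0.14, let-7e-5p 0.094, let-7b-5p 0.17, miR-106a-5p/miR-17-5p 0.044, miR-93-5p 0.0064 and miR-23a-3p 0.055. With library weights, miR-515-5p was 0.14, miR-4454 -0.29 and miR-720 -0.55. With median of ratios let-7a-5p was 0.038, and with the 100 highest miRNAs let-7a-5p was 0.049 and let-7b-5p 0.0091. With each library left out in turn, the range was -0.36 to 0.18 for miR-515-5p, -0.52 to 2.51 for miR-4454, -0.76 to 1.96 for miR-720, -0.28 to 0.22 for let-7a-5p, -0.48 to 0.18 for let-7b-5p, -0.41 to 0.071 for let-7e-5p and -0.048 to 0.37 for miR-512-5p; the lowest values but that of miR-515-5p and miR-512-5p came without siPRKRA replicate 2.

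The total over the graded probes, a log2 difference of 2.11, was 1.53 without miR-4454 and miR-720 and 1.42 with the median; leaving out each library gave 1.82 to 2.53, 0.94 to 1.99 and 0.75 to 1.94, the lowest each time without siPRKRA replicate 1. For the total over the mRNA rows, -0.12, these were -0.70 and -0.81, and leaving out each library gave -0.33 to 0.056, -0.98 to -0.30 and -1.17 to -0.35; without siPRKRA replicate 2 they were -0.33, -0.30 and -0.35. The difference in detected miRNAs, 41.7, was 8 at a fixed value of 30 and 37.3 at 30 counts after scaling by the graded probes. The share of matching signs, 99.1%, was 90.6% with scaling by the 100 highest miRNAs. The difference for miR-515-3p, 3.51, was 0.44 with background added back and 3.20 to 3.84 with each library left out. The limma adjusted p of miR-186-5p, 0.072, ranged over its alternatives from 0.0061 to 0.816, that of miR-193b-3p from 0.00068 to 0.46, and those of let-7b-5p, miR-302d-3p, miR-378e and miR-4516 from 0.014, 0.014, 0.022 and 0.014 to 0.997, 0.786, 0.786 and 0.80. Of all other values of named miRNAs and of C19MC under the alternatives, 685 kept their direction and side of the threshold, 28 were newly past it (11 with the graded probes, 7 with no filter) and 10 were no longer past it, all of them the C19MC list.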

Other observations

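The miRNA families not described above did not pass their list test. Of the miR-99, miR-100 and miR-125 family, with 4 tested members, the median log2 fold change was -0.09 (camera adjusted p = 0.935). The miR-30 family had a median of -0.08 over 5 members (0.977), the miR-15 and miR-16 family -0.22 over 3 (0.855), the miR-29 family -0.21 over 3 (0.897), and miR-26, miR-103 and miR-107 -0.33 over 3 (0.723). Epithelial miRNAs outside the miR-200 family had a median of 0.08 over 4 members (0.897). All tested 5p arms, 53 probes, had a median of -0.08 (0.977), and all tested 3p arms, 40 probes, one of -0.02 (0.897), so neither arm list passed. For the miR-30 family and the 5p arms the direction of the camera test was up, opposite to the median. Adjusted over the list alone in limma, 1 of the 5p arms passed (0.0359) and 0 of the members of the other lists in this paragraph.

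The tests of the next 2 paragraphs were chosen after the results were seen. Of the 14 miRNAs at the floor in all control and above it in all siPRKRA libraries, 6 were C19MC members. C19MC held 13 of the 44 named miRNAs at the floor in all control libraries. miR-515-3p had the highest mean siPRKRA value of the 14, but was not the highest in siPRKRA replicate 2. The pattern of the 14 may reflect less RNA in the control lanes together with background subtracted in excess. Per the labels the same mass of RNA was taken from each sample, which goes against less RNA in the control lanes. Relative to the graded control probes, however, the mRNA rows were 4.69-fold higher in siPRKRA than in control libraries (exact permutation p = 0.1). Hiding equal levels in the control libraries would take a median of 10.0 counts of excess subtraction judged from siPRKRA replicate 1 and 9.52 from replicate 3. From each of these, 0 of 14 miRNAs were over the upper bound of the estimate of 25 (18 to 33) from other miRNAs. Judged from replicate 2 the median was 34.2, with 7 of 14 over that bound. The estimate was made without replicate 2, so its bound may not hold for that library. Excess subtraction with less RNA in the control lanes and higher levels after PRKRA silencing both stay open. With the estimated excess added back, the median log2 fold change of the 14 was -0.33, 3 of them were above 0, and 0 had an adjusted p under 0.05. miR-515-3p went from 3.51 ± 0.59 (SE) to 0.44 ± 0.18 (SE), since the control values then start from the level added back instead of the floor. As none of its control values lay above the floor, both sizes depend on that starting level. The estimate of the excess itself assumes that no true change depends on abundance, and the miRNAs behind it were chosen by their siPRKRA level.

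A second hypothesis concerns the 6 tested miRNAs with a log2 fold change under -1, miR-144-3p, miR-371a-3p, miR-579, miR-378e, miR-302d-3p and miR-630, some of them named after their values were seen. Their estimates may come from counts that do not grow with the RNA in the lane and are then multiplied by a small factor. The 6 were picked by fold change from these same libraries, so ratios between the libraries are not independent of that choice. Within the siPRKRA group, the unscaled counts of replicate 1 over replicate 3 had a median ratio of 1.03 over these 6 (0.517 to 2.14). Over the other 100 tested miRNAs it was 2.09 (quartiles 1.92 and 2.29). miR-378e had 186 and 216 counts, while miR-630, at a ratio of 2.14, lay within those quartiles. For replicate 2 over replicate 3 the median ratio of the 6 was 0.945 (0.0120 to 1.23), against 0.404 (quartiles 0.308 and 0.518). Lower levels after PRKRA silencing cannot be told apart from this, because the degree of silencing in each library was not measured; the smallest of the 3 per-library median differences from the control libraries was -0.55, in siPRKRA replicate 2.

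The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For the count of miRNAs past adjusted p 0.05 they decide nothing, because the real split gave 0, which each of the 10 must equal or exceed; the highest other split also gave 0. The real split gave 17 miRNAs at an unadjusted p under 0.05 against 10 in the highest other split, so 1 of the 10 gave as many. It gave 1 shifted list against 2 in the highest other split, and 4 of the 10 gave as many.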
